A study of Rattus norvegicus with 6 samples.

How the data were processed

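Polyadenylated RNA of cultured rat vascular smooth muscle cells was sequenced in 6 libraries. The labels put 3 libraries in a MIAT knockdown group, and 3 libraries titled Scr with a wild-type genotype label form the control group, called Scr control here. Per the labels' protocols, small interfering RNAs and antisense oligonucleotides at 50 nM in all were left on the cells for 72 h. The labels carry this text for every library and do not state what the control cells received.

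The authors deposited a table of counts, whole numbers per gene symbol with no normalization, and a table of FPKM values (counts scaled by gene length and by the library's total). In the deposited tables, 100% of the FPKM values above 0 equalled the count divided by a single length per gene and by the library's total count, within a relative tolerance of 1e-06, so the deposited FPKM hold the same measurements as the counts plus the gene lengths. The aligner, the counting program, the strand setting and the genome build are not given in the sources used here. The table lists 18631 genes, of which 16604 symbols matched the RefSeq annotation of the GRCr8 assembly, 16532 of them protein-coding and 17 long noncoding. That annotation served for names only, and no coordinates are given because the authors' build is unknown. Miat, the targeted long noncoding RNA, was not analysed here, so the depth of the knockdown was not measured and the group labels could not be checked against it. The lists of mitochondrially encoded genes and of small nucleolar RNA host and nuclear long noncoding genes were not analysed here.

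Total counts ranged from 17793811 to 20121161 per library. Library sizes were normalized with TMM and genes with low counts removed with filterByExpr in edgeR 4.0.16 under R 4.3.3, which left 13423 genes. Levels are given as CPM after TMM normalization, with the SD over 3 libraries. The test chosen before the data were examined was edgeR's quasi-likelihood test of MIAT knockdown against Scr control with no further covariate and Benjamini-Hochberg adjustment over all tested genes at 0.05. The gene lists, the rule for the genes named, and the alternatives without the replicate block were also chosen before the data were examined. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

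The titles number the libraries of each group 1 to 3. After removal of the group means, same-numbered libraries deviated together, with correlations across genes of 0.68, 0.52 and 0.58 for pairs 1, 2 and 3, against -0.56 to -0.05 for differently numbered libraries. Deviations from a group mean cancel, so a positive value for a match lowers the others and the contrast is partly built in. With the means left in, the correlations were 0.980 to 0.985 against 0.959 to 0.976. Few ways to match 3 libraries with 3 exist, so a match to the numbers can also arise by chance. The pairing therefore comes from the data and the shared numbers, not from a statement in the labels, and it was decided before the calls of the fits were compared. The fit with the replicate number as a block, planned as an alternative, is given beside the fit without it. The words rose and fell refer to an adjusted p under 0.05 in the block fit of edgeR. The biological coefficient of variation was 19.7% without the block and 8.09% with it, on 4 and 2 residual degrees of freedom. Leaving out a pair leaves fewer, so a call that ends without a pair can reflect the loss of data as well as that pair. Within groups, counts of any 2 libraries differed by a chi-square of 21.6 to 89.8 per degree of freedom, so no library was a copy of another.

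Of 24 gene lists, 22 had at least 3 tested members. Each was tested with camera in limma 3.58.1 on the edgeR fit, with a preset correlation between genes of 0.01 and adjustment over the 22 lists, and again with an estimated correlation and with fry. The genes named are Dhx9, the 6 largest rises and the 6 largest falls among genes with adjusted p under 0.05, a mean of at least 5 CPM, a gene symbol and no overlap between the groups, and up to 3 members of each list with the largest absolute log2 fold change among those past the threshold, or the most abundant member where none passed. Because no gene passed without the block, the rule was applied to both fits. Some list members that the rule gives are not reported here, and list counts and medians include them. The alternatives were DESeq2 1.42.0, limma-voom, limma with a trend on log2(FPKM + 1) and log2(FPKM + 0.1), DESeq2 size factors or total counts as scaling, other low-count filters, a minimum fold of 1.5 in glmTreat, and leaving out each library. After seeing the data, the same choices were repeated with the block, each pair was left out, and a correction for gene length was added, a loess curve of span 0.5 fitted per library. List calls gained by another scaling or filter, in limma-voom, by the length correction or without a library or pair were tested again with an estimated correlation, and none of them held. With an estimated correlation camera also uses the residual degrees of freedom, 4 without the block and 2 with it. Few lists can pass on so few, so a lost call is by itself no evidence of correlation between genes. Without pair 3, the integrated stress list had an estimated correlation of -0.0026, below the preset. Its camera p still went from 1.2e-15 to 0.067.

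The scripts were tested on simulated data for the same comparison and 13423 genes, with 50 genes changed at each fold. Without the block, edgeR recovered 10% of 1.5-fold, 44% of 2-fold, 84% of 3-fold and 82% of 4-fold changes, with 0 false calls. With the block, it recovered 70%, 76%, 100% and 96%, with 11 false calls. The simulated counts took their pair effects and dispersions from the block fit, so pairing was true in them by construction. The higher recovery with the block is therefore no evidence that the real libraries are paired. In data simulated with a length trend, the correction lowered the false calls of the block fit from 364 to 15. The simulated trend was stronger than that in the data, with Spearman's rho between length and log2 fold change of -0.57 against -0.28. The 364 false calls are therefore not an estimate for these data.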

Results

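Gene expression was measured by RNA sequencing in rat vascular smooth muscle cells, the contractile cells of the vessel wall, in 3 libraries labelled MIAT knockdown and 3 labelled Scr control. MIAT is a long noncoding RNA, and the series title links it and the RNA helicase DHX9 to nucleolar homeostasis, mitotic progression and thickening of the vein wall. Total counts were 18173111, 18274521 and 18598394 in knockdown libraries 1 to 3 and 17793811, 18381954 and 20121161 in control libraries 1 to 3. The 10 most abundant genes took 8.32% to 9.62% of the counts in knockdown libraries and 10.3% to 13.7% in control libraries.

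Miat itself, the targeted gene, was not analysed here, so the level of the knockdown is not given and the groups are named by their labels. The libraries labelled MIAT knockdown separated from the controls along the second principal component, which held 25.9% of the variance. The leading component, with 42.5%, followed the replicate numbers instead, and control library 3 lay farthest along it. Same-numbered libraries were next to each other in order on this axis. Knockdown library 3, at 20.1, still lay nearer to knockdown library 2, at -1.71, than to control library 3, at 47.0.

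**Figure D1:**
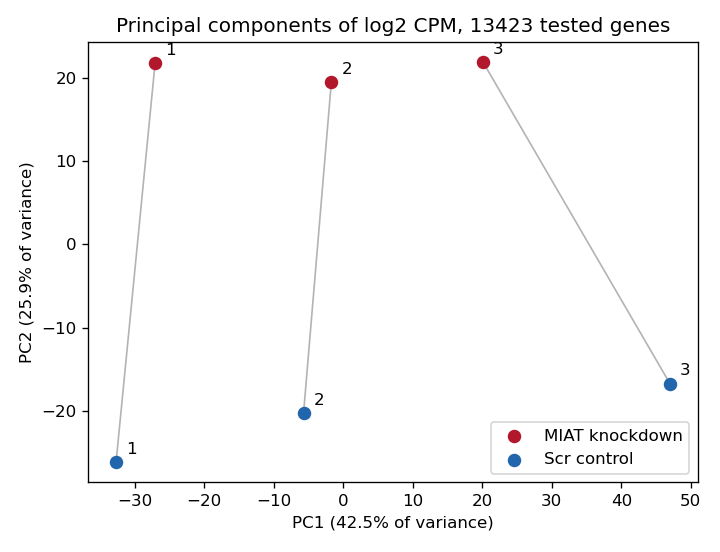
Principal components of log2 CPM of the 13423 tested genes, PC1 (42.5% of variance) against PC2 (25.9%), with MIAT knockdown libraries in red, Scr control libraries in blue and lines joining same-numbered libraries. The groups part along PC2, from 19.5 to 21.9 in the knockdown and -26.1 to -16.7 in the control libraries.

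The largest rises in the libraries labelled MIAT knockdown included a pair of phosphatase genes, and interferon-induced genes were among the largest falls. Dusp8 and Dusp10, phosphatases that switch off MAP kinases, rose from 3.60 ± 1.45 to 12.2 ± 2.93 CPM and from 21.6 ± 5.47 to 70.3 ± 24.0 CPM (SD, n = 3). Chac1, a glutathione-degrading enzyme of the stress response, rose 2.97-fold, Bbc3, which encodes the cell death factor PUMA, 2.70-fold, Smad7, an inhibitor of TGF-beta signalling, 2.65-fold, and Mroh6 2.68-fold. Rsad2, which encodes the antiviral enzyme viperin, fell from 22.1 ± 14.3 to 3.59 ± 1.48 CPM, Ifit3 from 7.88 ± 5.13 to 2.41 ± 0.910 CPM and Irf7, a regulator of interferon genes, from 17.4 ± 3.69 to 7.28 ± 0.816 CPM. Samd9 fell 2.53-fold, the protocadherin Pcdh17 3.70-fold and the aminopeptidase Lvrn 2.33-fold. The Ifit3 call ended without pair 1 (log2 fold change -1.06) and without pair 2 (-1.37), and the Lvrn call without pair 2 (-1.23).

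With the replicate block, edgeR's quasi-likelihood test called 2898 of 13423 genes at an adjusted p under 0.05, of which 1412 rose and 1486 fell. The median absolute log2 fold change of the called genes was 0.38, and 226 exceeded a 2-fold change, 116 upward and 110 downward. Without the block, the fit fixed in advance called 0 genes, with 2576 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.104. Of those 2576 genes, 2099 were called in the same direction with the block. On the unblocked design DESeq2 called 608 genes, 324 higher and 284 lower, all 608 of them called in the same direction with the block in edgeR, while limma-voom called 0, as did limma with a trend on log2 FPKM with either pseudocount and edgeR against a minimum fold of 1.5. With the block, DESeq2 called 1533 genes and a minimum fold of 1.5 left 23. The count was 1170 without pair 1, 983 without pair 2 and 4014 without pair 3. The smallest edgeR adjusted p was 5.7e-99 without pair 3 against 3.6e-04 with all pairs, so the variance estimate without a pair is unstable. Scaling by total counts moved the median log2 fold change of all genes by 0.107 and the share of called genes that were higher from 48.7% to 77.5% (2822 higher, 819 lower), so directions are relative to TMM scaling. The groups did not overlap in 3496 genes, 26.0% against 10% by chance for libraries that are not paired.

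**Figure D2:**
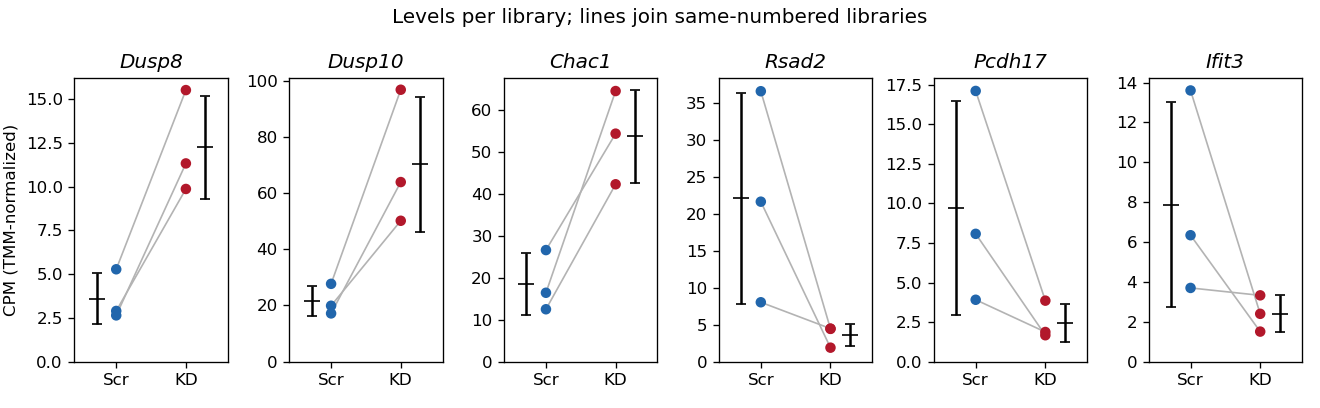
CPM after TMM normalization in each library for the 3 largest rises and the 3 largest falls named by the rule, with Scr control (Scr) in blue, MIAT knockdown (KD) in red, grey lines joining same-numbered libraries, and black bars giving the mean and SD of 3 libraries. Dusp8, Dusp10 and Chac1 were higher and Rsad2, Pcdh17 and Ifit3 lower in the knockdown library of each pair.

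Against a minimum fold of 1.5, 17 of the 23 genes were higher, and those named here, apart from Myc, are outside the naming rule and were chosen after their values were seen. The largest changes were in genes at low levels, the uncharacterized LOC108350996 at 12.4 ± 3.63 against 2.06 ± 0.707 CPM, Alpk3 at 3.76 ± 0.801 against 0.448 ± 0.284 CPM, Styk1 at 6.02 ± 2.54 against 0.910 ± 0.323 CPM, the linker histone gene H1f4 at 6.28 ± 2.48 against 1.27 ± 0.695 CPM and Nckap5 at 0.300 ± 0.223 against 3.41 ± 2.20 CPM. Reads of histone genes can be shared between near-identical copies. Many histone transcripts also lack a poly(A) tail, so libraries of polyadenylated RNA may not measure their level. Myc, a transcription factor of cell growth, rose from 51.1 ± 3.64 to 113 ± 17.3 CPM. Hmox1, the heme-degrading enzyme heme oxygenase 1, rose 2.31-fold and Gadd45a, a growth arrest and DNA damage gene, 2.08-fold. Among the 6 lower genes, the more abundant chemokine gene Ccl11 and the hyaluronan-binding protein Cemip had log2 fold changes of -1.12 and -1.18.

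Dhx9, the helicase named in the series title, stood at 177 ± 17.7 CPM in the knockdown and 206 ± 11.8 CPM in the control libraries (n = 3), a log2 fold change of -0.21 with a standard error of 0.096 and an edgeR adjusted p of 0.284. With the block the log2 fold change was -0.22 with a standard error of 0.055 and an adjusted p of 0.02504, and Dhx9 was lower in 3 of 3 pairs. This call ended with the block in DESeq2 (log2 fold change -0.23, adjusted p = 0.0525), without pair 1 (-0.22, 0.133) and without pair 2 (-0.25, 0.105), where the size of the change held. It also ended with total count scaling (-0.11, 0.159) and with the length correction (-0.17, 0.0905), where the change was smaller. Among 32 tested genes of DHX9-related helicases and double-stranded RNA binding proteins, 5 rose, 3 fell and 24 did not pass, with the same 5 and 3 when adjusted over the list alone. Hnrnpc rose by a log2 fold change of 0.35, while Adar, the RNA-editing enzyme, fell by 0.34. The Adar call ended without pair 2 (-0.39). The list median was 0.05, with a camera adjusted p of 0.177 without the block and 0.160 with it. The camera test passed without pair 3 (adjusted p = 0.0367), with total count scaling without and with the block (median 0.16 in both, adjusted p = 0.0295 and 0.0216) and with the block and no low-count filter (0.0402). These calls were lost at adjusted p = 0.533, 0.550, 0.544 and 0.595 with an estimated correlation. With the length correction and block 6 members rose and 1 fell.

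Genes of mitosis, a process named in the series title, and of cytokinesis were higher, with all 50 tested members above the control level in the fit of all libraries. With the block 45 rose, 0 fell and 5 did not pass, and 47 rose when adjusted over the list alone. Ccna2, which encodes cyclin A2, rose from 36.2 ± 5.98 to 60.4 ± 5.55 CPM, the kinetochore gene Spc25 rose 1.62-fold and Birc5, which encodes survivin, 1.59-fold. Mki67, the proliferation marker Ki-67 and the most abundant member, was at 147 ± 21.4 against 121 ± 22.6 CPM. Without the block 0 members passed over all genes in edgeR, and 40 were higher when adjusted over the list alone. The list median was 0.45 without and 0.46 with the block, with camera adjusted p = 1.8e-27 and 2.1e-25 at the preset correlation. The call was lost at adjusted p = 0.306 with an estimated correlation, 0.381 with the block as well.

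Of 45 tested genes of DNA replication and the G1/S transition, 35 rose, 0 fell and 10 did not pass with the block. Adjusted over the list alone, 40 rose with the block and 7 were higher without it. Ccne2, which encodes cyclin E2, rose from 15.5 ± 5.19 to 26.4 ± 5.50 CPM, and the polymerase subunit gene Pole2 and the origin recognition gene Orc1 each rose 1.69-fold. Rrm1, the large subunit of ribonucleotide reductase, rose 1.31-fold. Without pair 2 the calls of Pole2 (0.77) and Orc1 (0.88) ended, as did that of Pole2 without pair 1 (0.65). At 0.39 without the block, the replication list's median passed (camera adjusted p = 4.7e-15, and adjusted p = 0.389 with an estimated correlation).

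Genes of the nucleolus and ribosome biogenesis were also higher, by less. Of 68 tested members, 35 rose, 0 fell and 33 did not pass with the block, and adjusted over the list alone 41 rose and 1 fell. Ppan, a ribosome maturation factor, rose from 29.6 ± 2.75 to 55.0 ± 7.86 CPM, Taf1d, a component of the RNA polymerase I initiation machinery, rose 1.69-fold and Rrs1, a ribosome assembly factor, 1.55-fold. Ncl, which encodes nucleolin, was at 698 ± 51.3 against 618 ± 29.7 CPM, with an edgeR adjusted p of 0.0569 in the block fit. Without the block 26 members were higher when adjusted over the list alone. Nucleolar genes had a median of 0.23 in both fits, with camera adjusted p = 5.9e-15 without the block, and adjusted p = 0.306 with an estimated correlation, 0.381 with the block as well.

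Genes of cytosolic ribosomal proteins had a small positive median of 0.14, with 23 of 67 past the threshold upward, 0 downward and 44 not past in the block fit. Adjusted over the list alone, 31 rose and 1 fell with the block and 0 passed without it. Rps25 rose 1.29-fold, Rpl24 1.25-fold and Rpl11 1.23-fold, whereas Rplp0, the most abundant member, was at 1705 ± 145 against 1726 ± 151 CPM. Rpl24 and Rpl11 did not pass without pair 1 (log2 fold changes 0.28 and 0.29) or pair 2 (0.35 and 0.31). The camera adjusted p was 3.7e-05 without the block, and adjusted p = 0.714 with an estimated correlation. With the length correction and block the median was 0.01, the mean -0.0017 and the camera adjusted p 0.746, with 0 members higher and 3 lower past the threshold. The median was 0.25 with total count scaling, 0.09 without knockdown library 3 and 0.08 without control library 1. Reads of these genes can be shared with processed pseudogenes, so their values are uncertain.

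Matrix genes were lower in the libraries labelled MIAT knockdown. Of 42 tested genes of the extracellular matrix and the synthetic smooth muscle state, 26 fell, 0 rose and 16 did not pass with the block, and 30 fell when adjusted over the list alone. Thbs2, a matrix glycoprotein gene, fell from 2458 ± 843 to 1313 ± 305 CPM, the collagen gene Col12a1 fell 1.81-fold and the gelatinase gene Mmp2 by a log2 fold change of 0.59. Tnc, which encodes tenascin C and was the most abundant member, fell from 22024 ± 2485 to 14945 ± 1309 CPM. Without the block 13 members were lower when adjusted over the list alone. For matrix genes the median was -0.39 (camera adjusted p = 1.6e-11, and adjusted p = 0.306 with an estimated correlation), and -0.23 without control library 3.

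Genes of the contractile apparatus were lower as well. With the block 10 of 26 fell, 0 rose and 16 did not pass, and adjusted over the list alone 14 fell with the block and 0 passed without it. With the length correction and block 6 fell and 20 did not pass. Myh11, the smooth muscle myosin heavy chain, fell 1.42-fold, as did the integrin gene Itga8. Flna, which encodes filamin A, fell from 5788 ± 423 to 4220 ± 552 CPM. Contractile genes had a median of -0.24 without the block (camera adjusted p = 0.0014, and adjusted p = 0.673 with an estimated correlation). The call ended without knockdown library 3 (median -0.07, adjusted p = 0.176) and without control library 2 (-0.14, 0.0596), and the median was -0.38 without knockdown library 2 and -0.14 with total count scaling.

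Interferon-response genes had the lowest median of the 22 lists, -0.68 without and -0.73 with the block. With the block 25 of 40 fell, 1 rose and 14 did not pass, and adjusted over the list alone 29 fell and 2 rose. Besides Rsad2, the list's largest falls were Oasl, from 5.56 ± 5.21 to 1.06 ± 0.456 CPM, and Mx1, from 0.920 ± 0.198 to 0.263 ± 0.0518 CPM, a low level. Within pairs 1, 2 and 3 the log2 difference of Oasl was -2.97, -2.71 and 0.07, so it was not lower in pair 3. That of Mx1 was -1.68, -1.15 and -1.56, and the list median was -0.53, -0.72 and -0.61. Ifi27 fell from 152 ± 16.7 to 102 ± 23.3 CPM, and the riser was Zbp1, a sensor of nucleic acids, with a log2 fold change of 0.86. Oasl and Mx1 did not pass without pair 1 (-1.38 and -1.64) or pair 2 (-1.76 and -1.95). Without the block 21 members were lower when adjusted over the list alone. The camera adjusted p was 1.7e-18, and this was the only list that also passed at an estimated correlation, with adjusted p = 0.0265, a call lost with the block at adjusted p = 0.240. The estimated correlation was 0.018 without and -0.021 with the block, so a higher correlation does not account for that loss. The block fit has fewer residual degrees of freedom, 2 against 4. With fry the list passed in both fits (adjusted p = 0.0127 and 0.0149). In genes of at least 5 CPM the block median was -0.47.

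Growth factor response genes changed in both directions. Of 31 immediate early and serum response genes, 14 rose, 4 fell and 13 did not pass with the block, and 16 rose and 4 fell when adjusted over the list alone. Myc, Dusp5 and Junb rose 2.21-fold, 2.05-fold and 1.96-fold, and Ier3, the most abundant member, from 258 ± 90.9 to 389 ± 95.2 CPM, whereas Atf3 and Nr4a2, both transcription factor genes, fell by log2 fold changes of 0.69 and 0.57. The list median was 0.23 without the block (camera adjusted p = 1.8e-04, and adjusted p = 0.634 with an estimated correlation), with 2 members higher when adjusted over the list alone. The median was 0.16 without control library 3 (adjusted p = 0.165), which ended the call, and 0.52 without control library 1. With the block it was 0.25, and 0.39 without pair 2.

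Among 40 genes of the integrated stress and unfolded protein responses, 14 rose, 5 fell and 21 did not pass with the block. Adjusted over the list alone, 16 rose and 5 fell with the block and 5 were higher without it. Trib3, a pseudokinase gene of this response, rose 2.27-fold and Ppp1r15a, which encodes a regulator of translation recovery, from 99.1 ± 22.5 to 202 ± 41.4 CPM, while Calr, the chaperone calreticulin, fell by a log2 fold change of 0.21. The call of Trib3 ended without pair 2 (1.06). Stress response genes had a median of 0.14 without the block (camera adjusted p = 5.4e-04, and adjusted p = 0.306 with an estimated correlation). It was 0.25 with total count scaling, 0.09 without knockdown library 3, 0.07 without control library 1, 0.09 without control library 2 and 0.22 without control library 3.

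Of 31 p53 target genes, 10 rose, 3 fell and 18 did not pass with the block, and 12 rose and 3 fell when adjusted over the list alone. Bbc3 and the kinase gene Plk3 rose, Plk3 by 1.93-fold, whereas Cdkn1c, which encodes the cell cycle inhibitor p57, fell 2.54-fold. Without pair 1 the Cdkn1c call ended (-1.03). Ccng1, the most abundant member, was at 462 ± 74.6 against 483 ± 72.0 CPM. Over the p53 targets the median was 0.10 without the block (camera adjusted p = 0.0332, and adjusted p = 0.390 with an estimated correlation), with 2 members higher when adjusted over the list alone. This call ended in limma-voom (adjusted p = 0.126), without knockdown library 1 (0.146) and without control library 2 (median 0.06, adjusted p = 0.0554), and with the block the median was 0.02 without pair 1 and 0.21 with total count scaling.

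Inflammatory genes moved in opposite directions in different pairs. The median log2 difference of the 38 tested cytokine and NF-kB response genes was -0.46 in pair 1, -0.32 in pair 2 and 0.73 in pair 3, with 26, 29 and 4 members lower. With the block 2 rose, 2 fell and 34 did not pass, with 1 up and 2 down when adjusted over the list alone. The members with the largest changes past the threshold were Tnf, lower 4.24-fold at 0.783 ± 0.464 against 3.71 ± 3.23 CPM, the NF-kB inhibitor Tnfaip3, higher 1.84-fold, and the complement gene C3, lower 1.56-fold. Tnf did not pass without pair 1 (-1.68) or pair 2 (-1.71), nor C3 without pair 2 (-0.56). Ccl2, the most abundant member, was at 3927 ± 632 against 3706 ± 733 CPM. The list median was -0.23 without the block (camera adjusted p = 0.643). It was 0.31 without control library 1 (adjusted p = 0.0101) and -0.39 without control library 3 (6.4e-04). With the block it was 0.18 without pair 1 (0.0206), 0.11 without pair 2 and -0.39 without pair 3 (2.6e-20), where 23 members fell. With an estimated correlation these 4 calls were lost, at adjusted p = 0.631, 0.611, 0.741 and 0.491 in the same order. Macrophage and leukocyte markers followed the same order of pairs, with medians of -0.95, -0.51 and 0.22 over 7 tested members.

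The TGF-beta response list was mixed, with 5 of 24 genes up, 4 down and 15 not past in the block fit and 5 up and 5 down when adjusted over the list alone. Besides Smad7 and Junb, its largest change was in Ltbp3, a latent TGF-beta binding protein gene, which fell 1.43-fold. The median was 0.01 without the block, -0.0046 with DESeq2 size factors and 0.07 with the block (camera adjusted p = 0.643 and 0.261). It turned to -0.04 without knockdown library 1 or control library 3, and with the block to -0.0066 without pair 1.

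Metabolic lists moved little. Of 26 genes on the cholesterol biosynthesis list, 1 rose, 3 fell and 22 did not pass. Lss fell 1.32-fold, and Lpin1, a lipid phosphatase gene that is on the list but outside that pathway, 1.43-fold. The list gave the same 1 and 3 when adjusted over its members alone. Its median was -0.13 without the block (camera adjusted p = 0.128) and -0.12 with it (0.0474, and adjusted p = 0.588 with an estimated correlation). The blocked call ended with total count scaling (median -0.01), with a minimum of 5 CPM, without pair 1 and without pair 3 (median -0.05), and the median was -0.18 without pair 2. The Lpin1 call ended without pair 1 (-0.46) and pair 2 (-0.50), and the Lss call without pair 1 (-0.33). Unblocked, the list passed without knockdown library 3 (median -0.31, adjusted p = 0.0028) and without control library 1 (-0.27, 9.7e-04), calls lost at adjusted p = 0.646 and 0.594 with an estimated correlation, and its median turned to 0.0037 without knockdown library 1 and 0.04 without control library 3. Cyp51, its most abundant member, was at 206 ± 56.0 against 228 ± 80.9 CPM. Of 31 glycolysis and hypoxia genes, Vegfa rose 1.18-fold and 3 fell, among them Hk1 and Aldoa, with 27 not past and the same counts over the list alone. Without pair 1 or pair 2, Hk1 (-0.25 and -0.29), Vegfa (0.17 and 0.26) and Aldoa (-0.16 and -0.22) did not pass. Gapdh was at 2109 ± 275 against 2117 ± 176 CPM. The glycolysis median was -0.08 in both fits (camera adjusted p = 0.223 and 0.162), turned to 0.03 with total count scaling and without knockdown library 1, and the list passed without knockdown library 2 (median -0.13), without control library 1 (-0.16) and, with the block, with the length correction (-0.11, where 5 members fell), calls lost at adjusted p = 0.737, 0.594 and 0.577 with an estimated correlation. Of 47 nuclear-encoded oxidative phosphorylation genes, 4 rose, 2 fell and 41 did not pass, with 0 when adjusted over the list alone. Cycs rose 1.22-fold, Ndufa4 rose 1.18-fold and Ndufb10 fell 1.18-fold, while Atp5f1b was at 794 ± 40.9 against 781 ± 17.7 CPM. The calls of Cycs ended without pair 1 (0.30) and pair 2 (0.33), and those of Ndufa4 (0.25, 0.29 and 0.17) and Ndufb10 (-0.24, -0.28 and -0.19) without any 1 of pairs 1, 2 and 3. The median was 0.07 in both fits (camera adjusted p = 0.128 and 0.105), passed with total count scaling (0.17), without knockdown library 1 (0.08) and with no low-count filter (0.08), and with the block with total count scaling (0.18), with no low-count filter (0.08), in limma-voom (0.07) and without pair 1 (0.08). These calls were lost with an estimated correlation, at adjusted p from 0.437 to 0.653. With the length correction and block the median was -0.04, with 1 member up and 3 down.

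Markers of other cell types were mostly at low levels or lower in the knockdown libraries. Of 13 adventitial fibroblast markers 8 fell, 0 rose and 5 did not pass with the block, and 9 fell when adjusted over the list alone, against 1 without the block. Lum, which encodes lumican, fell from 413 ± 23.0 to 283 ± 26.9 CPM, Pdgfra, a growth factor receptor gene, 1.49-fold and Dpt, at 5.29 ± 4.32 against 8.70 ± 8.44 CPM, 1.54-fold, while Dcn, the decorin gene, fell by a log2 fold change of 0.34. Dpt did not pass without any 1 of pairs 1, 2 and 3 (-0.67, -0.72 and -0.45), and without the block it was 0.45 without control library 3. These matrix genes are also expressed by smooth muscle cells, and their list moved with the matrix list above. The median was -0.47 (camera adjusted p = 0.0030, and adjusted p = 0.389 with an estimated correlation), and the call ended without control library 3 (median -0.21, adjusted p = 0.0616). Of 10 endothelial markers 0 rose and 2 fell with the block, Kdr at 2.25 ± 1.32 against 4.58 ± 2.87 CPM and Eng at 184 ± 45.2 against 243 ± 54.3 CPM, with 8 not past, and 1 rose and 2 fell over the list alone. The endothelial median was -0.27 (camera adjusted p = 0.223). The Kdr call ended without pair 1 (-0.94) and pair 2 (-1.15).

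Of 7 macrophage and leukocyte markers Cd74 fell and 6 did not pass, with 3 down when adjusted over the list alone. Cd74 was at 0.348 ± 0.180 against 1.48 ± 1.23 CPM, and Cd14 at 13.4 ± 0.867 against 13.4 ± 0.210 CPM. The leukocyte median was -0.42 (camera adjusted p = 0.158), -0.77 without control library 3 (adjusted p = 0.0019), 0.0024 without control library 1 and, with the block, -0.84 without pair 3 (0.0023) and 0.04 without pair 1. With an estimated correlation the calls without control library 3 and without pair 3 were lost, at adjusted p = 0.505 and 0.491. Of 7 neural and Schwann cell markers Ngfr fell and 6 did not pass, with 1 down when adjusted over the list alone. Ngfr was at 0.749 ± 0.385 against 2.63 ± 1.85 CPM and Tubb3, a tubulin gene, at 65.5 ± 25.4 against 92.4 ± 63.0 CPM. Neither Cd74 nor Ngfr passed without pair 1 (-1.47 and -1.51) or pair 2 (-1.49 and -1.62). The neural median was -0.50 without the block (camera adjusted p = 0.128, and with fry 0.0144). With the block the fry call was lost at adjusted p = 0.0666. Camera calls came under total count scaling (adjusted p = 0.0372) and, with the block, without pair 2 (median -0.53), with total count scaling (0.0234) and with the length correction (0.0434). These calls were lost at adjusted p = 0.327, 0.571, 0.356 and 0.420 with an estimated correlation. The 3 adipocyte and mesothelial markers included Msln, at 8.74 ± 3.51 against 10.9 ± 4.63 CPM, and 0 passed in edgeR in either fit (median 0.05, camera adjusted p = 0.973). Msln passed with the block without pair 3 (-0.44), and the median of these 3 ranged from -0.15 to 0.29 without 1 library. Of 9 osteochondrogenic markers Runx2, a bone transcription factor gene, rose 1.29-fold and Col11a1 fell 1.37-fold, with 7 not past, and 2 rose and 1 fell over the list alone. Its median of -0.03 and mean of 0.10 had opposite signs (camera adjusted p = 0.624). The median ranged from -0.31 to 0.30 without 1 library, and Runx2 did not pass without pair 1 (0.28) or pair 2 (0.40), nor Col11a1 without pair 2 (-0.57).

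**Figure D3:**
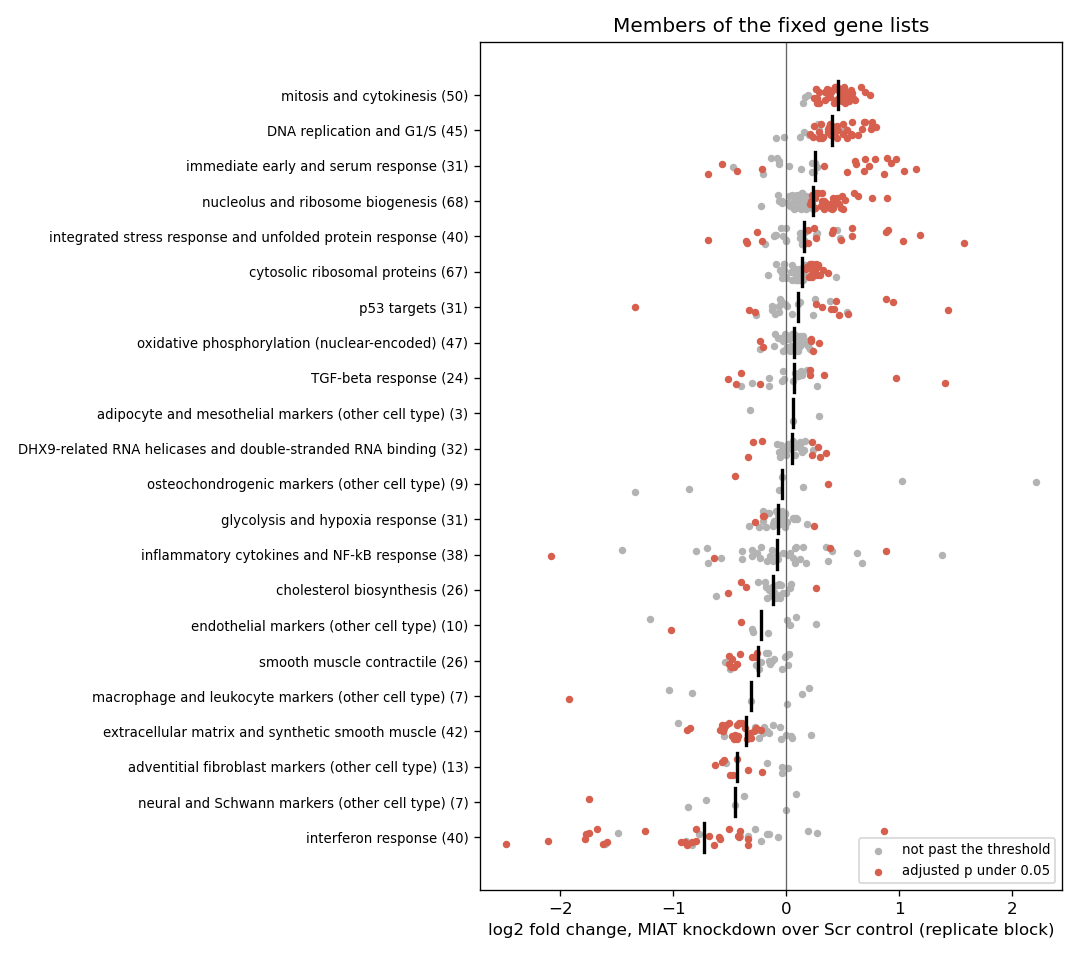
Log2 fold change of each member of the 22 tested lists in the block fit, MIAT knockdown over Scr control, with the number of tested members in brackets, red for adjusted p under 0.05, grey for members not past it, and a black bar at the median. Mitosis lies highest with a median of 0.46 and the interferon response lowest with -0.73.

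Fold changes went with gene length. Length here is the single length per gene behind the deposited FPKM, with a median of 3159 bases. The spans of the genes in the genome were not measured. Across genes, which are not independent replicates, Spearman's rho between length and the log2 fold change was -0.28 with the block, and -0.18, -0.23 and -0.29 within pairs 1, 2 and 3. In the shortest decile of genes the median log2 fold change was 0.12, with 211 genes up and 20 down, and in the longest decile -0.17, with 61 up and 349 down. With the length correction and block 2295 genes passed, 1263 up and 1032 down, of which 1974 were called in the same direction without the correction.

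**Figure D4:**
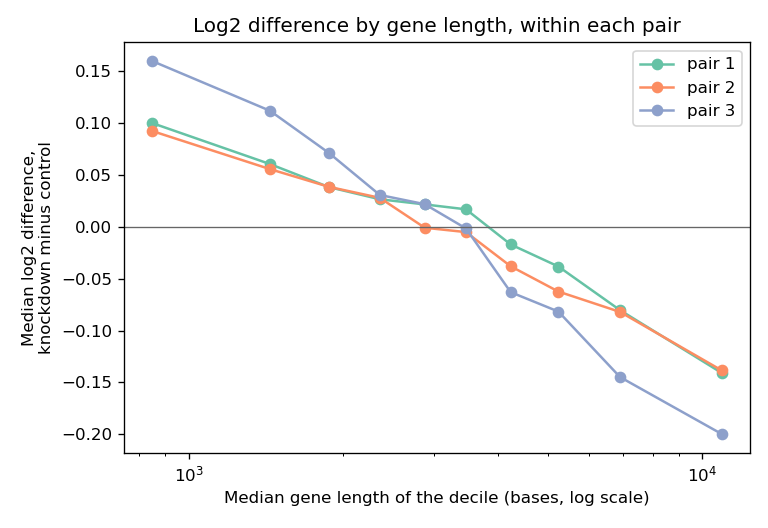
Median log2 difference, knockdown minus control library, against the median gene length in bases (log scale) for each decile of the tested genes, with a line for each pair of same-numbered libraries. In each pair the shortest genes were higher, from 0.09 to 0.16, and the longest lower, from -0.20 to -0.14.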

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

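The alternatives with the replicate block other than the block fit itself, and the length correction, were chosen after seeing the data. The number of genes called without the block was 0 in edgeR under each scaling and filter, in limma-voom and without any 1 library, but 608 with DESeq2 and 2898 with the replicate block. With the block it was 1533 with DESeq2 and 23 against a minimum fold of 1.5, which tests a stricter hypothesis. Without 1 pair it was 983 to 4014, on fewer residual degrees of freedom. Dhx9 passed at -0.22 with the replicate block. The medians of the mitosis list (0.45, with the block 0.46) and the nucleolus list (0.23 in both fits) do not move with the set test, but their calls ended with an estimated correlation and with fry. Without the block 104 comparisons of a named gene and 13 of a list passed only under an alternative, and 27 of a list lost a call. With the block 78 comparisons of a named gene and 27 of a list lost theirs. At the preset correlation the replicate block itself changed the camera call of the cholesterol list and of no other list.

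The signs that turned are given here. Total count scaling moved the median of all genes by 0.107, and the FPKM are scaled by the same library totals. Turns under total counts and under FPKM therefore follow from that shift and are not separate evidence. For the other turns the cause was not tested. With the length correction and block, Ccl2 was -0.039, Atp5f1b -0.033 and Cd14 -0.065, against 0.088, 0.022 and 0.0032 with the block alone. With total count scaling Rplp0 was 0.091, Ccng1 0.039 and Gapdh 0.10, and on log2(FPKM + 1) and log2(FPKM + 0.1) they were 0.0904 and 0.0904, 0.0414 and 0.0416, and 0.098 and 0.098. Gapdh was 0.0045 with no low-count filter. Cd14 was -0.0062 with DESeq2 size factors, -0.0030 at a minimum of 5 CPM and -0.0027 in DESeq2. Among lists without the block, TGF-beta was -0.0046 with DESeq2 size factors, inflammatory 0.011 in limma-voom, glycolysis 0.033 and osteochondrogenic 0.066 with total counts, and adipocyte and mesothelial -0.33 with no filter. With the block, inflammatory was 0.027, glycolysis 0.030 and osteochondrogenic 0.064 with total counts, osteochondrogenic 0.034 at a minimum of 5 CPM, oxidative phosphorylation -0.040 with the length correction, and adipocyte and mesothelial -0.39 with no filter.

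Without 1 library in turn, the ranges were Rplp0 -0.077 to 0.050, Ccl2 -0.023 to 0.25, Ccng1 -0.18 to 0.054, Cyp51 -0.35 to 0.17, Gapdh -0.11 to 0.077, Atp5f1b -0.0013 to 0.065, Ddx5 -0.0074 to 0.037, Cd14 -0.050 to 0.038, Tubb3 -0.83 to 0.21, Msln -0.64 to 0.067 and Dpt -1.63 to 0.45. For lists they were TGF-beta -0.042 to 0.062, inflammatory -0.39 to 0.31, cholesterol -0.31 to 0.040, glycolysis -0.16 to 0.035, leukocyte -0.77 to 0.0024, adipocyte and mesothelial -0.15 to 0.29 and osteochondrogenic -0.31 to 0.30. Without 1 pair, in the block fit, they were TGF-beta -0.0066 to 0.054, inflammatory -0.39 to 0.18, leukocyte -0.84 to 0.042, adipocyte and mesothelial -0.091 to 0.32 and osteochondrogenic -0.17 to 0.053. Miat has no value under any setting because it was not analysed here.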

Other observations

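The 10 gene families in the next paragraphs, the length test of the ribosomal protein genes, the test of the longer genes and the tests that leave out 1 pair were chosen only after related values had been seen. Several families of RNA and protein production were higher in the libraries labelled MIAT knockdown. Of 74 tested mitochondrial ribosomal protein genes 21 rose and 0 fell in the block fit of edgeR (median log2 fold change 0.19, and with the length correction 7 rose and the median was 0.10), led by Mrpl47 at 15.3 ± 1.99 against 9.91 ± 1.89 CPM (SD, n = 3). Among 26 genes of small nuclear ribonucleoproteins and LSm proteins 14 rose and 0 fell (median 0.25, with the length correction 7 and 0.19), Lsm5 by 1.56-fold and Snrpd1 from 41.2 ± 0.253 to 57.4 ± 1.12 CPM. Of 10 RNA exosome genes 6 rose (median 0.39, with the length correction 2 and 0.29), Exosc6 from 8.38 ± 0.948 to 21.9 ± 4.36 CPM. Of 33 histone genes 9 rose (median 0.44, with the length correction 8 and 0.32), of 8 CCT chaperonin genes 3 rose (0.16, with the correction 2 and 0.13), and of 37 genes of proteasome subunits and assembly chaperones 2 rose and 1 fell (0.12). The proteasome median was 0.02 with the length correction (camera adjusted p = 0.892), with 1 up. Most families were matched by gene symbol. Reads of histone genes can be shared between near-identical copies. Many histone transcripts lack a poly(A) tail, so the histone values from polyadenylated RNA may not measure the expression of these genes.

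Families of the cell surface and the lysosome were lower. Of 40 tested protocadherin and FAT cadherin genes 15 fell and 0 rose (median -0.66, with the length correction 11 and -0.57), including Fat1, from 1305 ± 55.6 to 819 ± 85.2 CPM. Of 42 lysosomal genes 27 fell and 0 rose (median -0.28, and -0.31 with 27 down after the length correction), such as Lamp1, from 661 ± 72.7 to 555 ± 63.7 CPM. Among 11 cation channel genes 6 fell and 1 rose (median -0.31), Cacna1c, the L-type calcium channel, from 67.2 ± 6.64 to 38.5 ± 5.26 CPM and Ryr3 by 3.05-fold, and after the length correction 5 fell and the channel median was -0.15. Of 20 dual-specificity phosphatase genes 7 rose and 1 fell (median 0.02, with the length correction the same counts and 0.01). All 10 families passed camera at the preset correlation in the block fit without the length correction (adjusted p from 1.2e-12 to 0.0115) and none did with an estimated correlation (adjusted p from 0.151 to 0.560). Without the block 0 members of any family passed over all genes in edgeR, and the small nuclear ribonucleoprotein and LSm family was the only one to pass camera with an estimated correlation (adjusted p = 0.0385). None of the medians changed sign with DESeq2 size factors or total counts, but total counts moved them to 0.30 for the mitochondrial ribosomal, 0.22 for the proteasome, 0.27 for the CCT, 0.13 for the phosphatase, -0.17 for the lysosomal and -0.20 for the channel family.

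The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Without the block 10 of the 10 splits gave as many genes as the real one, which gave 0, and the highest of the others was 0, a comparison of zeros that shows nothing. At an unadjusted p under 0.05 the real split gave 2576 genes and the highest of the others 1261. Of the 4 splits that part all 3 pairs, 1, the real one, gave as many as 2898 genes with the block, and the highest of the others, in which 1 pair has its labels exchanged, was 0. Such an exchange moves any consistent group difference into the residual, so the 0 does not estimate the number of false calls.

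The mitosis and nucleolus lists were higher in the knockdown libraries. With the length correction and block the medians were 0.45 (bootstrap interval 0.39 to 0.49) and 0.23 (0.15 to 0.28). Without the correction they were 0.46 and 0.23. Bootstrap intervals here and below resample genes within the same 6 libraries, so they do not measure the spread between libraries. The lists had median lengths of 3201.5 and 2368 bases, where the trend is small. Deciles with median lengths of 2354.5 and 3464.5 bases had median log2 fold changes of 0.026 and -0.0035. The correction could therefore hardly have lowered the list medians, but a trend of this size does not account for them as a whole. Nor does 1 pair carry the mitosis rise, since the mitosis median nearest 0 without a pair was 0.39. The nucleolus median was 0.26, 0.17 and 0.30 within pairs 1, 2 and 3. A hypothesis, not tested here, is that more of the cells in the knockdown group were dividing. Counts of dividing cells beside untreated cells would test it, but would not tell faster from slower division. A difference in culture density or in library preparation between the groups stays open, as the labels name no batch and Miat was not analysed here.

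The interferon list was lower in the knockdown libraries. Leukocytes among the cells are argued against by Ptprc, carried by all leukocytes, at a mean of 0.0092 CPM. Other markers were present, here in CPM without TMM scaling. Mrc1 was at 3.66 in the knockdown and 7.31 in the control libraries, and Cd68 at 4.20 and 7.09. Csf1r, at 5.53 and 4.98, and Cd14, at 13.9 and 12.9, were not lower. The list's median length was 2660.5 bases, where the length trend is small, so the length correction could hardly move its median log2 fold change. That median was -0.73 with the correction and block (interval -0.91 to -0.44), and -0.62 without the pair whose removal brought it nearest 0. A candidate explanation is that the oligonucleotides of the groups differ in how they trigger interferon genes, and another is an effect of MIAT itself. With no untreated group these remain open.

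Long genes, by the length behind the FPKM and not by their span in the genome, were lower and short genes higher in the knockdown libraries. The rank correlation between gene length and log2 difference was -0.18 in the pair nearest 0, and -0.20 (interval -0.22 to -0.18) among the 6711 genes longer than the median, so neither 1 pair nor short growth genes alone account for the trend. The small rise of the ribosomal protein genes may be part of it, since their median was 0.013 (interval -0.013 to 0.038) with the length correction and block against 0.14 before, and 533 other genes of like length had a median of 0.13. A difference in RNA quality or library preparation between the groups was not tested and stays open, as does a response of long genes to the knockdown. The share of G and C bases was not tested, as no genome was used here.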
